A study of Mus musculus with 6 samples.

How the data were processed

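RNA of 6 samples of mouse hippocampal slice cultures was measured, 3 treated with vehicle and 3 with sAPPα, and per the labels each sample held the slices of 4 mice. The deposited values are intensities: per the labels, the authors computed the signal of each probe set with Affymetrix MAS 5.0 and scaled each array to a target of 2500. The 2% trimmed mean of the deposited columns was 2501 to 2502. Labelling, scanning and background settings beyond this are not given in the sources used here, and detection calls were not used here.

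Of 12488 probe sets, 66 were controls. Of the other 12422, the platform annotation gave 1 gene symbol for 10833, several for 396 and none for 1193. Symbols were updated through Entrez IDs with a table of RefSeq genes, which matched 10817, and no gene was named from a probe set with several symbols. No reference genome was used, so no positions are given. Control probe sets were left out, and of the rest the upper 60% by mean log2(signal + 100) over the 6 arrays were tested, a floor at a mean signal of 691. This left 7453 probe sets, of which 6679 had 1 symbol, for 5668 genes. Log2 differences and slopes refer to log2(signal + 100), and the values were not normalized again.

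Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Treatment was fitted as sAPPα against vehicle on all 6 arrays. Days in culture (11, 13 or 15) were fitted as a slope with treatment as a covariate. The deviations of same-numbered samples from their group means correlated across genes at 0.37, 0.62 and 0.65 for the 15-day, 13-day and 11-day pairs. The highest r with a sample of another number was 0.39 for the 15-day and 13-day pairs, so the 15-day pair did not exceed it. The labels name no culture preparation, and the replicate number was used as a block in an alternative. The 3' to 5' ratios and hybridization controls were compared with exact permutation tests.

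The design, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined, except where the text says otherwise. Ttr, Igf2, Igfbp2 and App were always reported. Up to 12 genes per direction were named for treatment and 8 for days. They were taken by largest difference among those past the threshold, and the places left were filled by smallest unadjusted p among genes with the same sign in all 3 pairs, or in both treatments for days. Up to 4 members of each list were named by smallest unadjusted p, for days only from lists past the test. The 24 lists held 806 genes, of which 477 were measured, and 23 lists had the 5 measured members needed for a test. They covered cell types (choroid plexus, meninges, ependyma, neurons, interneurons, subfields, astrocytes, microglia, oligodendrocytes, endothelium) and signalling, stress and metabolic pathways. Lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, the brightest, with an estimated correlation and fry beside it. Genes can be in more than 1 list.

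The alternatives tried were pseudocounts of 1 and 500, no filter and a filter at the upper 40%, quantile normalization, median centring, eBayes without trend or robust, the replicate block, days as a covariate, no treatment covariate, an estimated correlation, the mean over a gene's probe sets, and leaving out each array. Leaving out the 11-day pair, array weights and lists without Ttr were added after the data were seen. The procedure was tested on simulated data with 100 probe sets changed 2-fold and 100 changed 4-fold. The treatment fit called 1 and 24 of these and 3 unchanged probe sets, the block called 1 and 35 with 1 unchanged, and the fit on days called 0 and 0 with 0 unchanged.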

Results

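Gene expression was measured in organotypic hippocampal slice cultures, which are thin slices of mouse hippocampus kept alive on porous inserts. The slices came from male C57B6/SJL mice at postnatal day 15. Secreted amyloid precursor protein alpha (sAPPα) is the soluble ectodomain that alpha-secretase cleaves from the amyloid precursor protein. Slices received sAPPα at 1 nM or buffer alone (vehicle) for the last 24 h. Each treatment had 3 samples, pooled from 8 to 12 slices of 4 mice, and 1 array was read per sample. The samples numbered 1, 2 and 3 had been in culture for 15, 13 and 11 days, so each vehicle sample had an sAPPα sample of the same culture age. The design therefore asked which transcripts differ after sAPPα, and, as a second comparison, which transcripts follow the time in culture.

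Every array reported 12488 probe sets, and the number of arrays limits the precision of every value. The 2 arrays of the 11-day cultures stood apart. The 4 arrays of the 13-day and 15-day cultures correlated with each other at r = 0.946 to 0.972 across probe sets. Vehicle 3 correlated with those 4 at 0.622 to 0.692, and sAPPα 3 at 0.811 to 0.857. Hybridization controls, bacterial transcripts added at fixed amounts, were 3.04 times the median array on vehicle 3 and 1.41 times on sAPPα 3, against 0.566 to 1.13 on the others. The ratio of 3' to 5' signal, a measure of the length of the labelled RNA, was 6.67 and 5.04 for Gapdh on these 2 arrays and 1.70 to 2.91 elsewhere. For Actb it was 3.26 and 4.93, against 2.79 to 3.19. Within the pairs of the same culture age, the sAPPα array was lower than the vehicle array in all 3 for the Gapdh ratio and the hybridization controls, and in 1 of 3 for the Actb ratio. The tests of the groups could not pass a threshold of 0.05. The log2 ratio was higher by 0.23 in sAPPα for Actb (exact permutation p = 0.6, two-sided) and differed by -0.24 for Gapdh (exact permutation p = 0.7). The hybridization controls differed by -0.67 on the log2 scale (exact permutation p = 0.5), and the smallest p possible with 3 against 3 arrays is 0.1.

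**Figure D1:**
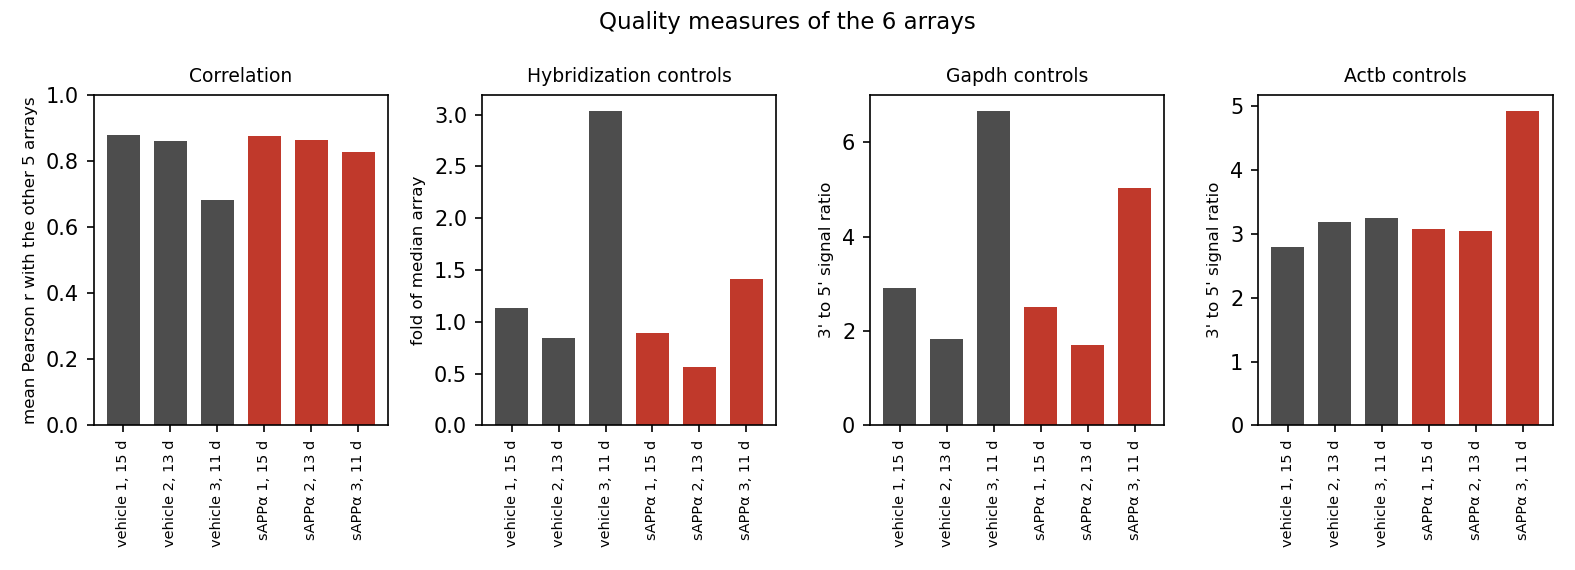
Bars show 1 value per array for 4 quality measures: the mean Pearson correlation with the other 5 arrays, the signal of the hybridization controls as a fold of the median array, and the 3' to 5' signal ratios of Gapdh and Actb, with vehicle arrays in grey and sAPPα arrays in red. The Gapdh ratio is 6.67 on vehicle 3 and 5.04 on sAPPα 3, and at most 2.91 on the other 4 arrays.

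The first comparison set the 3 sAPPα arrays against the 3 vehicle arrays. Ttr (Entrez 22139) encodes transthyretin, a thyroid hormone and retinol carrier produced in brain by the choroid plexus. Its signal was 477, 558 and 664 on vehicle arrays 1, 2 and 3. On the sAPPα arrays it was 20098, 92.6 and 9089.5, so it was far above vehicle in the 15-day and 11-day pairs and below it in the 13-day pair. The log2 differences of the 3 pairs were 5.13, -1.77 and 3.59, and their mean of 2.32 ± 1.53 (SE) was 4.98-fold on the log2(signal + 100) scale. It was 1.01 without sAPPα 1 and 4.36 without sAPPα 2. This did not exceed the spread between arrays (limma adjusted p = 0.999, unadjusted p = 0.170, and 0.0863 unadjusted with the replicate number as a block).

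Igf2 (Entrez 16002), which encodes insulin-like growth factor 2, had a signal of 3434 ± 1081 (SD, n = 3) in vehicle and 7973 ± 2966 (SD, n = 3) in sAPPα. The 2 groups did not overlap, and the log2 difference was 1.18 ± 0.36 (SE), or 2.27-fold. The pair differences were 0.64, 0.61 and 2.30, and the mean was 0.62 without the 11-day pair. A second Igf2 probe set lay below the signal filter, with means of 137 and 95.4. Igfbp2 (Entrez 16008), the gene of a secreted protein that binds insulin-like growth factors, was at 4934 ± 622 (SD, n = 3) in vehicle and 7401 ± 837 (SD, n = 3) in sAPPα. Its log2 difference was 0.58 ± 0.23 (SE), and the 3 pairs gave 0.58, 0.54 and 0.61. App (Entrez 11820), the gene of the precursor itself, had a log2 difference of 0.24 ± 0.68 (SE). Its signal was 14879 on vehicle 3 and 28290 on sAPPα 3, against 65587 to 75564 on the other arrays, and without the 11-day pair its difference was -0.10. Leaving out 1 array gave it -0.54 (vehicle 3) to 0.67 (sAPPα 3). None of the 3 genes passed the test over all probe sets (limma adjusted p = 0.999 for each). In simulated data the treatment fit called 1 of 100 probe sets changed 2-fold, so missing this threshold does not show that a gene is unchanged. The unadjusted limma p was 0.0116 for Igf2, 0.0383 for Igfbp2 and 0.733 for App. With the replicate number as a block it was 0.0114, 0.009996 and 0.378. These values are not adjusted for the number of genes tested.

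**Figure D2:**
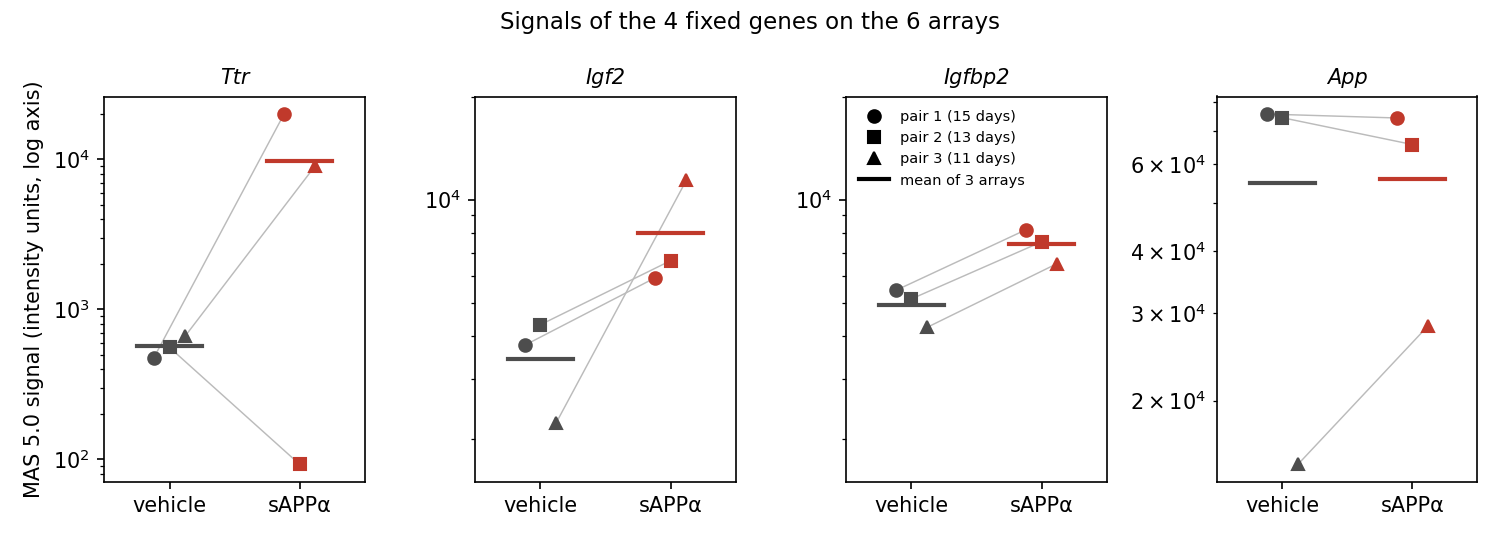
Points show the MAS 5.0 signal (intensity units, log axis) of Ttr, Igf2, Igfbp2 and App on each of the 6 arrays, with thin lines joining arrays of the same culture age and thick bars at the mean of the 3 arrays of a group. Ttr reaches 20098 and 9089.5 on 2 sAPPα arrays and 92.6 on the other, while Igf2 and Igfbp2 are higher in sAPPα in all 3 pairs.

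Among the other genes that were higher in sAPPα in all 3 pairs, Lgi4 (Entrez 243914), a secreted protein gene needed for myelination by peripheral glia, had the smallest unadjusted p. Its signal was 711 ± 166 (SD, n = 3) in vehicle and 2022 ± 289 (SD, n = 3) in sAPPα, a log2 difference of 1.40 ± 0.36 (SE). Gpx3 (Entrez 14778) and Gsta4 (Entrez 14860), which encode the extracellular glutathione peroxidase and a glutathione transferase, differed by 0.92 ± 0.32 and 1.37 ± 0.49 (SE). Fxyd1 (Entrez 56188), a regulator of the sodium pump, differed by 0.70 ± 0.25. Id1 (Entrez 15901), an inhibitor of helix-loop-helix transcription factors, differed by 1.08 ± 0.43. Crabp2 (Entrez 12904), a carrier of retinoic acid, differed by 0.96 ± 0.40. Without the 11-day pair, Gsta4, Id1 and Crabp2 were at 0.71, 0.58 and 0.50, and Id1 was at 0.66 without vehicle 3 alone. The remaining named genes with higher values were Calml4 (Entrez 75600) at 1.18, Pcp4l1 (Entrez 66425) at 1.08, Atp5k (Entrez 11958) at 0.87 (0.42 without the 11-day pair) and Tmem176a (Entrez 66058) at 0.55. On vehicle 2 the signals of Lgi4 (518.5), Calml4 (641.6) and Pcp4l1 (414.9) were below the floor of 691, not shown above background. On vehicle 3 the same held for Gsta4 (312.4), Id1 (556.7), Crabp2 (541.2) and Pcp4l1 (470.9). The differences of these genes are therefore no measure of fold change.

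Of the genes lower in sAPPα in all 3 pairs, Pcp2 (Entrez 18545), a Purkinje cell gene that modulates G protein signalling, had the smallest unadjusted p. Its signal was 3292 ± 1340 (SD, n = 3) in vehicle and 889 ± 96.3 (SD, n = 3) in sAPPα, a log2 difference of -1.71 ± 0.36 (SE). Fam220a (Entrez 67238) differed by -1.22 ± 0.38 and Sugp2 (Entrez 234373) by -0.85 ± 0.28 (SE). Pik3r2 (Entrez 18709), a regulatory subunit of phosphoinositide 3-kinase, had a signal of 2437 in vehicle and 1202 in sAPPα. St3gal5 (Entrez 20454), the synthase of ganglioside GM3, differed by -1.46 ± 0.50, by -0.65 without the 11-day pair and by -0.97 without sAPPα 3. Prkar1b (Entrez 19085), a regulatory subunit of protein kinase A, differed by -1.21 ± 0.49, and P2rx6 (Entrez 18440), a purinergic receptor subunit, by -1.58 ± 0.66. Hoxb6 (Entrez 15414), a homeobox gene, Sct (Entrez 20287), the gene of the hormone secretin, and Pcbp4 (Entrez 59092), an RNA-binding protein gene, were lower by values of -1.70, -1.17 and -0.84. Cops2 (Entrez 12848) and Wdr48 (Entrez 67561) had differences of -1.20 and -0.91, but a second probe set of each gene went the other way, at 0.54 and 0.14. Without the 11-day pair Prkar1b, Pcbp4, Cops2 and Wdr48 were at -0.73, -0.44, -0.55 and -0.57, and without vehicle 3 alone Prkar1b and Wdr48 were at -0.71 and -0.55. On sAPPα 1, 2 and 3 the signals were 353.7, 230.6 and 1066.9 for P2rx6 and 173.6, 729.6 and 622.1 for Hoxb6. They were 557.3, 540.8 and 729.9 for Fam220a and 766, 637.9 and 292 for Cops2. St3gal5 was at 482.5 on sAPPα 3. Signals under the floor of 691 were not shown to be above background. The differences of P2rx6, Hoxb6, Fam220a, Cops2 and St3gal5 are therefore no measure of fold change.

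None of these genes passed limma's test over the 7453 probe sets. The count at adjusted p under 0.05 was 0, and the smallest adjusted p was 0.999. At unadjusted p under 0.05 there were 31 probe sets, 15 higher and 16 lower, where chance alone would give 373. At unadjusted p under 0.01 there were 3, where chance would give 74.5: Pcp2, Lgi4 and a probe set that the annotation assigns to more than 1 gene and that is therefore left unnamed (1.17 ± 0.28, SE, higher in all 3 pairs), chosen after its values were seen. With the replicate number as a block, limma's count at unadjusted p under 0.01 was 22 and the count at adjusted p under 0.05 stayed at 0, with 214 at unadjusted p under 0.05. Without the 11-day pair these counts were 23, 0 and 118. The 2 groups did not overlap at 324 probe sets, 4.35% of those tested, where chance gives 10%. All 3 pairs had the same sign at 2035 probe sets, 27.3%, where chance gives 25%. The chance values of 373, 74.5 and 10% assume independent arrays, but same-numbered samples shared deviations. The other splits of 3 against 3 arrays that part all 3 pairs gave 23, 26 and 29 probe sets at unadjusted p under 0.05. The 31 of the real split was near these counts.

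Of the gene lists, 2 of 23 passed limma's camera test for treatment, both upwards. All 6 measured choroid plexus epithelium genes were higher in sAPPα on average (camera adjusted p = 0.00244, median log2 difference 0.73). With an estimated correlation between genes the adjusted p was 0.825, and fry gave p = 0.0826. Beyond Ttr and Calml4, a calmodulin-like gene, the members were Ace (1.05 ± 0.51, SE), which encodes angiotensin-converting enzyme, Atp1b1 (0.40 ± 0.42), a sodium pump subunit, Lbp (0.25 ± 0.23), the lipopolysaccharide-binding protein gene, and Col8a1 (0.18 ± 0.42), a collagen gene. The list median was 0.43 in the 15-day pair, 0.30 in the 13-day pair and 1.13 in the 11-day pair, and in the same 3 pairs the Gapdh ratio and hybridization controls were lower in sAPPα. Over the other 15 choroid plexus genes on the array, filtered ones included and Ttr left out, the median was 0.69, 0.09 and -0.45 in the same order, with 7 of 15 higher in the 11-day pair, so the sign there depends on the filter. Ttr and Ace were below the signal floor on every vehicle array and on sAPPα 2, so their differences are no measure of fold change. Without that pair Atp1b1 was at 0.11 and Col8a1 at -0.029. The camera adjusted p was 0.0110 without Ttr, 0.110 without vehicle 2 and 0.0710 without the 11-day pair, whose arrays stood apart in the quality measures, and ranged from 1.32e-08 to 0.825 over the alternatives. Ttr is also in the APP processing list.

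The respiratory chain list, the subunits of the mitochondrial complexes that make ATP, had 30 of 39 genes higher in sAPPα (camera adjusted p = 0.0120, median 0.19). The adjusted p was 0.825 with an estimated correlation, and fry gave p = 0.122. Atp5k and Atp5g1, both ATP synthase subunits, had values of 0.87 ± 0.37 and -0.87 ± 0.48 (SE). Uqcrh of complex III and Ndufb9 of complex I had 0.41 ± 0.25 and 0.46 ± 0.29. Without the 11-day pair Atp5k, Atp5g1 and Ndufb9 were at 0.42, -0.36 and 0.091. The list median was 0.12 and 0.03 in the 15-day and 13-day pairs and 0.45 in the 11-day pair, again with the Gapdh ratio and hybridization controls lower in sAPPα in each. The call was lost after quantile normalization (adjusted p = 0.269), without the 11-day pair (0.132), without vehicle 1 (0.291) and without sAPPα 3 (0.208), and the adjusted p ranged from 0.00153 to 0.825 over the alternatives. In these 2 lists and in the other 21, no member passed limma's threshold, over all probe sets or adjusted over the list alone.

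**Figure D3:**
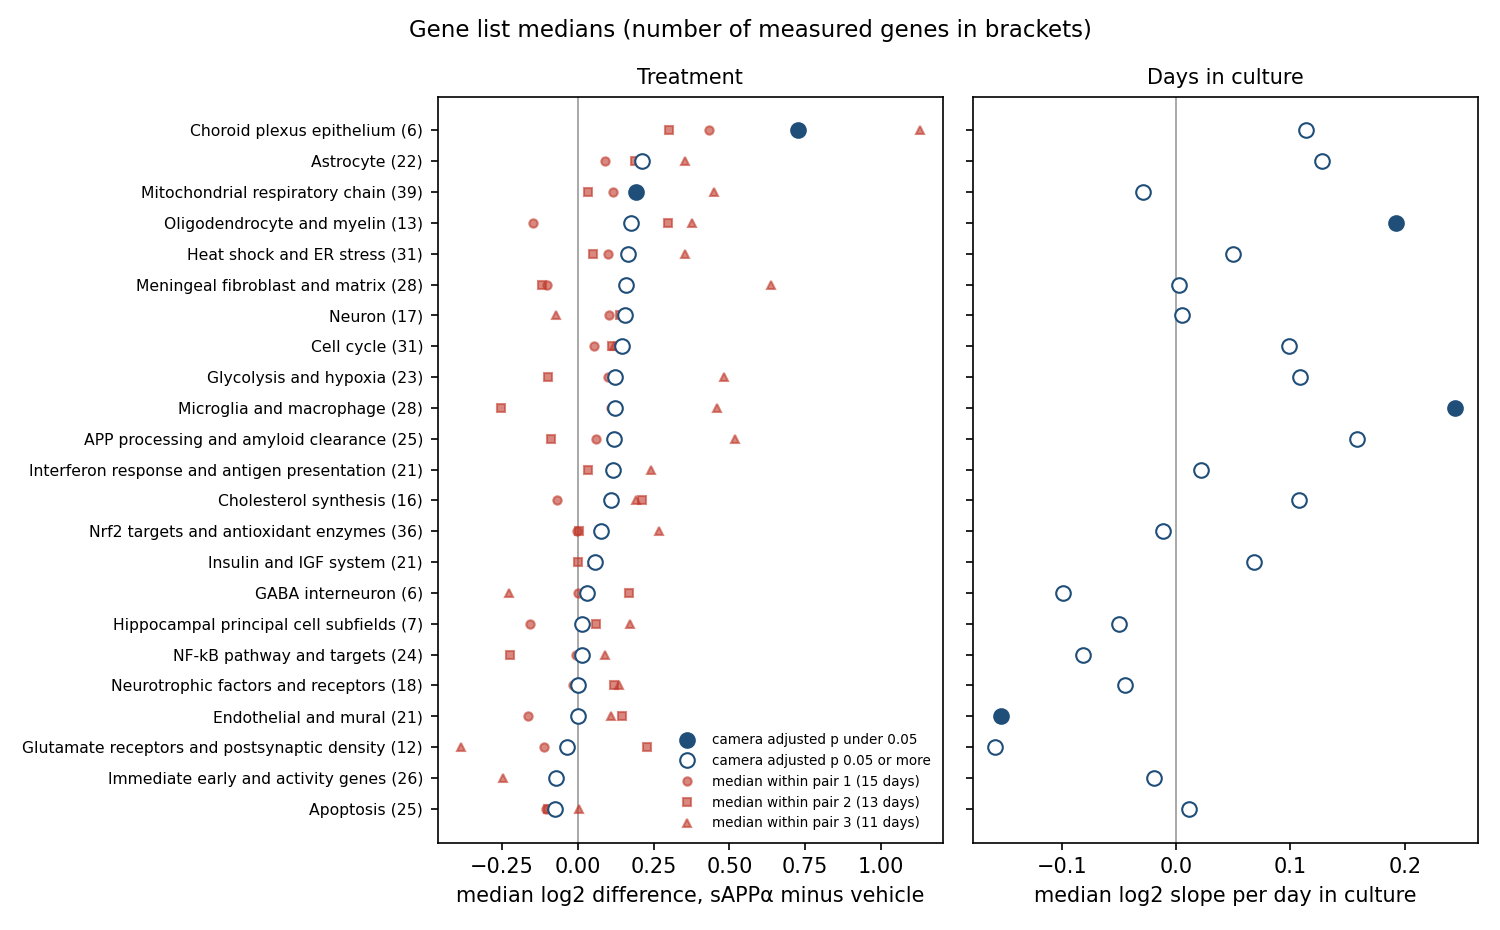
Large circles show the median over each list's measured genes (numbers in brackets) of the log2 difference between sAPPα and vehicle, left, and of the log2 slope per day in culture, right, filled where the camera adjusted p is under 0.05. Small red symbols show the median within each pair of the same culture age: the choroid plexus median is 0.43, 0.30 and 1.13 in pairs 1, 2 and 3, and the microglial slope median is 0.24 per day.

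Lists of signalling and stress genes did not pass the camera test for treatment on all 6 arrays. Of the 83 genes named for treatment, 52 moved by more than 1.5 times without the 11-day pair. When 1 array was left out, 53 moved by more than 1.5 times, so genes without brackets can also depend on 1 array. Some list members also had signals below the floor of 691, such as Icam2 (500.9) and Hspa1b (315.9) on vehicle 3 and Grin2b (143.9) on sAPPα 2. Differences of such genes are no measure of fold change. For those of the 52 in the lists below, the value without the 11-day pair stands in brackets after the gene's own. The meningeal fibroblast and matrix list had 21 of 28 genes higher (adjusted p = 0.148). It holds Igf2 and Igfbp2, and Apod, a lipid carrier, and the collagen gene Col6a2 had 0.42 (0.26) and 0.35 (-0.037). The list median was -0.10 and -0.12 in the 15-day and 13-day pairs and 0.64 in the 11-day pair. The interferon and antigen presentation list had 15 of 21 genes higher (adjusted p = 0.148), with Psme1 at 1.14 (0.27), Ifitm3 at 0.47 (0.11), Ifi204 at 0.49 (0.24) and Psmb8 at 0.37 (0.058). Immediate early and activity genes, which neurons induce on stimulation, had 15 of 26 members lower (adjusted p = 0.148). Zfp36 was at -0.58 (-0.34), Nfil3 at -0.74, Pim1 at -0.57 (-0.29) and Plk3 at -0.51. Plk3 was at -0.043 without vehicle 3 and at -0.89 without sAPPα 3. The insulin and IGF list had 12 of 21 genes higher (adjusted p = 0.673), and beside Igf2 and Igfbp2 its leading members were Pdpk1, a kinase upstream of Akt, at -0.56 and Igfbp3 at 0.57 (0.064). Genes of APP processing and amyloid clearance were higher in 20 of 25 cases (adjusted p = 0.339), with Cdk5 at 0.86 (0.22), Apbb1 at 0.54 (-0.015) and Plat at 0.47 (0.051) after Ttr. Nrf2 targets and antioxidant enzymes had 21 of 36 genes higher (adjusted p = 0.486). After Gpx3 and Gsta4, Prdx4 was at 0.48 (0.041) and Gclc at -0.38 (-0.20).

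With brackets used in the same way, apoptosis genes had 13 of 25 members lower (camera adjusted p = 0.673). The adaptor genes Tradd and Fadd were at 0.59 and -0.43, the receptor gene Tnfrsf1a at 0.38 (0.063) and the survival gene Bcl2 at -0.67. Tradd was at 0.39 without vehicle 1. Bcl2 was at -0.078 without vehicle 3 and at -1.20 without sAPPα 3. NF-kB pathway genes were split at 12 higher and 12 lower (camera adjusted p = 0.893). Bcl3 was at 0.79 (0.23), Sod2 at 0.31 (0.12), Nfkb2 at 0.36 (0.13) and Ikbkb at -0.35 (-0.15). Without sAPPα 3 alone Bcl3, Sod2 and Nfkb2 were at 0.27, 0.19 and 0.057. Bcl3 and Sod2 were at 1.27 and 0.49 without vehicle 2, and Nfkb2 at 0.54 without sAPPα 2. Heat shock and ER stress genes had 20 of 31 higher (adjusted p = 0.339), with Hspe1 at 0.35 (0.17) and Hspa1b at 0.66 (0.011). Glycolysis and hypoxia genes had 16 of 23 higher (adjusted p = 0.148), with Pfkp at 0.71 (0.45) and Hk1 at 0.45 (0.16). Cell cycle genes had 19 of 31 higher (adjusted p = 0.486), with Cdc25c at 0.92 and Lig1 at -1.06 (-0.30). Cholesterol synthesis genes had 10 of 16 higher (camera adjusted p = 0.673), with Scd1 at 0.36 and Mvk at -0.37 (-0.23). Scd1 was at 0.70 without vehicle 1 and at 0.16 without vehicle 2. Neurotrophic factors and receptors had 9 of 18 higher (adjusted p = 0.914), with Mdk at 0.46 and Fgf1 at -0.87 (-0.28).

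The lists of neurons, glia and vessels did not pass on all 6 arrays, but some passed with 1 array left out. The calls with arrays left out used only the preset correlation, which treats list genes as nearly independent. Their p-values reflect spread over genes more than spread between cultures. Brackets after gene values again leave out the 11-day pair. Neuronal genes had 12 of 17 higher (adjusted p = 0.467), with Thy1 at 0.58 (0.10) and Camk2b at 0.48, and the list was called up without vehicle 3 (adjusted p = 0.0484). Astrocyte genes had 17 of 22 higher (adjusted p = 0.476), although the glutamate transporter gene Slc1a2 was at -0.73 (-0.23) and the connexin gene Gja1 at 0.33 (0.13). Without sAPPα 3 the astrocyte list was called up and the endothelial list down (adjusted p = 0.0461 for each). Oligodendrocyte genes had 12 of 13 higher (camera adjusted p = 0.273), with Mog at 0.30 (0.18) and Mal at 0.16. The list was called up without vehicle 1 (camera adjusted p = 0.00162). Mog was at 0.63 without vehicle 1 and at 0.087 without vehicle 3. Mal was at 0.25 without vehicle 1 and at 0.055 without vehicle 2. Microglial genes had 21 of 28 higher (adjusted p = 0.914), with Cx3cr1 at -0.51 (-0.23) and Cd14 at -0.26 (-0.11). This list was called down without vehicle 3 (camera adjusted p = 2.13e-06), and up without vehicle 2 (0.0151) or sAPPα 3 (0.0461). Endothelial and mural genes had 10 of 21 higher (adjusted p = 0.860), with Ramp2 at 0.97 (0.33) and Icam2 at 0.75 (-0.037). GABA interneuron genes were split at 3 and 3 (adjusted p = 0.673), with Pvalb at -0.40 (-0.23) and Cort at -0.58 (0.032). Hippocampal subfield genes had 4 of 7 higher (adjusted p = 0.819), with Man1a at 0.53 (0.097) and Neurod2 at -0.47. Glutamate receptor and postsynaptic genes had 5 of 12 higher (camera adjusted p = 0.673), with the receptor subunit gene Grin2b at -0.98. Grin2b was at -0.31 without vehicle 3 and at -1.54 without sAPPα 3. The median, the mean and the test differed in sign for the GABA interneuron, subfield, endothelial, NF-kB and microglial lists. Of the other lists, without sAPPα 3 the glycolysis and heat shock lists were called up (adjusted p = 0.0461 for each), glycolysis also without vehicle 2 (0.00498), and the meningeal list was called up without sAPPα 1 (0.0122). Only 3 ependymal genes were measured, too few to test.

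The second comparison followed the time in culture over 11, 13 and 15 days, with 1 vehicle and 1 sAPPα array at each age. Mobp (Entrez 17433), a gene of central myelin, had the smallest unadjusted p among the positive slopes. Its vehicle signal was 4663, 9729 and 17865 at 11, 13 and 15 days, and its sAPPα signal was 6846, 13160 and 19647. The slope was 0.43 ± 0.06 (SE) log2 units per day, or 3.27-fold over the 4 days. The other 3 Mobp probe sets had slopes of 0.51, 0.20 and 0.14, the last on the brightest of them, where the slope within sAPPα was -0.0036. Other genes with a positive slope in both treatments were Fyn (Entrez 14360), a kinase of myelinating cells and synapses, at 0.38 ± 0.07 and H2-K2 (Entrez 630499), of the class I histocompatibility region, at 0.73 ± 0.14. Further ones were Myh9 (Entrez 17886), Slain1 (Entrez 105439), Timp3 (Entrez 21859) and Tubb4a (Entrez 22153) at 0.44, 0.47, 0.42 and 0.36. Hcn2 (Entrez 15166), a pacemaker channel gene, had 0.39 on this probe set and -0.13 on another. Negative slopes were led by Erdr1 (Entrez 170942) at -0.53 ± 0.08, with vehicle signals of 54455, 38859 and 12019. Vwf (Entrez 22371), the gene of the endothelial von Willebrand factor, had a slope of -0.45 ± 0.09, and Adam28 (Entrez 13522), a metalloprotease gene, -0.59 ± 0.10. Cbx2 (Entrez 12416), Tacr2 (Entrez 21337), Kcnn1 (Entrez 84036) and Elf4 (Entrez 56501) had -0.75, -0.67, -0.60 and -0.55. Nudcd2 (Entrez 52653) had -0.69, and its other probe set 0.26. At 15 days the vehicle and sAPPα signals were 234.7 and 232.5 for Cbx2 and 203.4 and 225.9 for Tacr2. They were 425.1 and 344.3 for Kcnn1 and 271.5 and 368 for Nudcd2. All of these signals, and that of Elf4 in sAPPα (440.9), were below the signal floor and not shown to be above background. The slopes of these genes are therefore no measure of fold change. Without the 11-day arrays the slopes were 0.30 for H2-K2, 0.22 for Fyn, 0.25 for Myh9, 0.29 for Slain1, 0.15 for Timp3, -0.30 for Adam28, -0.27 for Vwf, -0.91 for Kcnn1, -0.37 for Nudcd2 and -0.31 for Elf4. H2-K2 had 0.48 without vehicle 3 alone.

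By limma, 0 probe sets passed adjusted p under 0.05 for days in culture, and the named genes shared the smallest adjusted p of 0.237. At unadjusted p under 0.05 there were 1489, where chance would give 373, and at unadjusted p under 0.01 there were 267, 181 with positive and 86 with negative slopes. The chance value assumes independent arrays, but same-numbered samples shared deviations. Setting vehicle 1, vehicle 3 and sAPPα 3 against the rest gave 1757 and 383. That split keeps the samples numbered 3, the youngest cultures, on the same side. An effect of age could raise its counts too, so it cannot decide whether the excess over 373 comes from age. The excess alone does not show an effect of culture age, because the control ratios of the samples numbered 3 also stood apart. Leaving out vehicle 2 brought 739 probe sets to adjusted p under 0.05, but left the slopes as they were, such as 0.43 for Mobp and 0.73 for H2-K2. An array of the middle age carries no weight in the slope. Only the spread around the slope and the number of arrays changed. Of the probe sets at unadjusted p under 0.05, 59.8% had positive slopes as deposited and 70.1% after median centring, which moved the median change of all genes over the 4 days from 0.01 to 0.14. In a model with an interaction of treatment and days, limma called 0 probe sets at adjusted p under 0.05 and 136 at unadjusted p under 0.05. The labels name no culture preparation, so an effect of preparation cannot be told apart from culture age if same-numbered samples were prepared together.

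Of the lists, 3 of 23 passed the camera test for days. Microglia and macrophage genes had positive slopes in 27 of 28 cases (camera adjusted p = 0.000377, median slope 0.24 per day). The adjusted p was 0.901 with an estimated correlation, for this list and for the 2 that follow, and fry gave p = 0.235 for this list. In the microglial list 0 genes passed in limma adjusted over the list alone or over all probe sets, with 9 at unadjusted p under 0.05. The leading members were the tetraspanin gene Cd9 (0.47 ± 0.12, SE), the oxidase gene Cybb (0.47 ± 0.15), Mpeg1 (0.43 ± 0.14) and Cd53 (0.43 ± 0.15). Without the 11-day arrays, whose control ratios stood apart, the call turned to negative slopes between 13 and 15 days (camera adjusted p = 4.01e-12). This fit had 4 arrays and used only the preset correlation, so its p reflects spread over genes more than spread between cultures. The same limit holds for the other list calls with arrays left out. The slopes of Cd9, Mpeg1 and Cd53 were then -0.023, -0.16 and -0.21, and that of Cybb 0.020. The Cybb signals on vehicle 3 (433.9) and sAPPα 3 (227.7) were below the signal floor and not shown to be above background. Its slope over all arrays is therefore no measure of fold change. Over the alternatives the adjusted p ranged from 4.01e-12 to 0.901.

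Oligodendrocyte and myelin genes had positive slopes in 12 of 13 cases (camera adjusted p = 0.00427, median slope 0.19). The unadjusted p of fry was 0.0252. In this list 6 genes passed adjusted over the list alone and 0 over all probe sets, and limma gave 7 at unadjusted p under 0.05. Qk (0.47 ± 0.10, SE), an RNA-binding regulator of myelin transcripts, Ugt8a (0.80 ± 0.20), which makes the myelin lipid galactosylceramide, Cldn11 (0.30 ± 0.08), of the myelin tight junctions, and Gsn (0.25 ± 0.07), the gelsolin gene, led it. Between 13 and 15 days alone the list was also called up (camera adjusted p = 1.58e-05), with smaller slopes of 0.070 for Qk, 0.12 for Ugt8a, 0.16 for Cldn11 and 0.11 for Gsn. Ugt8a had 0.49 without vehicle 3 alone. Its signals on vehicle 3 (61.4) and sAPPα 3 (515.9) were below the signal floor and not shown to be above background. Its slopes over all arrays and without vehicle 3 are therefore no measure of fold change. The adjusted p was 0.0826 without vehicle 1 and 0.0554 with the filter at the upper 40%, and over the alternatives it ranged from 1.58e-05 to 0.901.

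Endothelial and mural genes had negative slopes in 16 of 21 cases (camera adjusted p = 0.0130, median slope -0.15). The unadjusted p of fry was 0.246. Adjusted over the list alone, 2 genes passed, and over all probe sets 0, with 5 at unadjusted p under 0.05 by limma. Beside Vwf, Pecam1 (-0.47 ± 0.12, SE), an endothelial adhesion gene, Des (-0.34 ± 0.12), the muscle filament gene desmin, and Kdr (-0.31 ± 0.11), a receptor of vascular endothelial growth factor, led it. At 15 days the sAPPα signals of Pecam1 (469.3) and Kdr (686.5) were below the signal floor and not shown to be above background. The slopes of Pecam1 and Kdr over all arrays are therefore no measure of fold change. Without the 11-day arrays the call turned to positive slopes (camera adjusted p = 0.00925), with Pecam1 at -0.26 and Des at -0.058, and without sAPPα 3 the adjusted p was 0.294, with a range of 0.000121 to 0.901 over the alternatives.

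The other 20 lists did not pass for days on all 6 arrays. The closest were APP processing (18 of 25 positive, camera adjusted p = 0.0787), glycolysis (18 of 23 positive, 0.0986) and heat shock genes (23 of 31 positive, 0.0986). Next were the astrocyte list (16 of 22 positive, 0.118) and the NF-kB list (15 of 24 negative, 0.118). Without the 11-day arrays, 11 lists passed at the preset correlation, the only one used there. The astrocyte (camera adjusted p = 0.000111) and glycolysis (3.25e-05) lists were then called down, against their direction on all arrays. NF-kB (0.00343), respiratory chain (0.00343) and interferon genes (0.0370) were called down, and cholesterol synthesis (0.00589), cell cycle (0.00616) and choroid plexus genes (0.00999) up. With 1 array left out, the APP processing list was called up without vehicle 2 (0.0258), sAPPα 1 (0.0279), sAPPα 2 (0.0283) or sAPPα 3 (0.0401). Glycolysis was called up without vehicle 1 (0.0300), vehicle 2 (0.0391) or sAPPα 1 (0.0279), and astrocytes up without sAPPα 1 (0.0279). The NF-kB and respiratory chain lists were called down without vehicle 3 (0.00971 for each). The median, the mean and the test differed in sign for the apoptosis, neuron, subfield, interferon, neurotrophic, immediate early, Nrf2 and meningeal lists.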

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

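All tests of explanations in this part were chosen only after the result was seen, except the test of a gradual change with days in culture.

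Among list members left out by the signal filter, 13 signals on sAPPα arrays were above the floor and more than 2-fold above the highest vehicle array. On sAPPα 1 these were Kl (3.68 times the highest vehicle signal), Car12 (2.97) and Folr1 (2.60), all from the choroid plexus list, and on sAPPα 2 it was Ccnd2 (2.57). On sAPPα 3 they were Cnp (6.09), Ccnd2 (4.29), Gria1 (3.55), Fmod (3.45), H2-Eb1 (3.11), Ogn (2.94), Syp (2.26), Rsad2 (2.21) and Prim1 (2.21). Except for H2-Eb1 (899), the highest vehicle signal was below the floor of 691 and not shown to be above background. Those ratios and their order are therefore no measure of fold change. In the opposite direction 28 signals of vehicle arrays stood above the highest sAPPα array in this way, 27 of them on vehicle 3.

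The Ttr signal was high on sAPPα 1 and sAPPα 3 and not on sAPPα 2. Scaling is argued against, as the mean log2 difference of these 2 pairs was still 4.59 after quantile normalization. Choroid plexus tissue in the slices of sAPPα 1 may be a source: the other 15 choroid plexus genes on the array had a median pair difference of 0.69, at percentile 99.98 of 10000 random lists of the same size and similar signals, with 12 higher, although most of these genes were left out by the filter. For sAPPα 3 the percentile was 38.14 with a median of -0.45 and 7 of 15 higher, so members that went both ways left tissue and other sources unable to be separated. An effect of sAPPα on Ttr in every culture stays open, because the signal of 92.6 on sAPPα 2 is a single array.

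Igf2 and Igfbp2 were higher in the sAPPα array of all 3 pairs, by a mean of 0.59 over the pairs of 15 and 13 days. More meningeal tissue there is argued against, since 26 other meningeal genes had a median of -0.066 (SD 0.24 over genes), with 8 higher. In the 11-day pair, where Igf2 differed by 2.30, the whole meningeal list had a median of 0.64, so meningeal tissue stays open there. Choroid plexus tissue in the 13-day pair may contribute and stays open. The other 15 choroid plexus genes had a median of 0.09 there, at percentile 77.13, with 10 higher, while Ttr, at -1.77, is 1 gene on 1 array. In the 15-day pair these 15 genes had 0.69, at percentile 99.98 with 12 higher, so choroid plexus tissue may contribute there. In the 11-day pair they had -0.45, at percentile 38.14 with 7 higher, which leaves it open. Chance among the probe sets tested stays open, as the smallest adjusted p of the pair of genes with the replicate block was 0.818, and an effect of sAPPα may stand beside it.

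The 11-day arrays stood apart from the other 4. Less labelled RNA may have contributed, as the hybridization controls were 2.49-fold those of the other arrays, and so may shorter RNA, as the Gapdh ratio was 2.66-fold that of the others and the Actb ratio 1.32-fold. A gradual change with age predicted that changes from 11 to 13 days and from 13 to 15 days, taken across the treatments, correlate above 0.1 across genes both ways round, and its absence was to show as both below 0 with an r above 0.1 between treatments for 13 to 15 days. The values were -0.22 and -0.40 (mean -0.31) and 0.28, but that bound was wrong. Arrays of the same age shared deviations across treatments (r = 0.67 for 11 to 13 days). The 13-day arrays also enter both changes with opposite sign. This alone gives a negative r, about -0.22 if the shared deviations were equally large at all 3 ages. The 11-day arrays stood apart from the other 4, so an equal size is not given and the test cannot decide. A gradual change with age and RNA quality therefore cannot be told apart here.

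The 6 arrays have 10 splits of 3 against 3, too few for a share under 0.05. For probe sets at adjusted p under 0.05 the real value was 0 and the highest other 0, with 10 of 10 splits as large, and at unadjusted p under 0.05 limma gave 31 for the real split. At unadjusted p under 0.01 the real value was 3 and the highest other 383, with 7 of 10 as large. That count came from setting vehicle 1, vehicle 3 and sAPPα 3 against the rest, which keeps the 11-day arrays together and points to a structure of the samples. Without the block, the other splits that part all 3 pairs gave 0 to 2. With the replicate block the real value was 22, and those splits gave 7, 8 and 21. For gene lists the real value was 2 and the highest other 4, with 8 of 10 as large, and up to 2 among the other splits that part all 3 pairs.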

How the results depend on the processing

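The fits without the 11-day pair, with array weights and without Ttr in the lists were chosen only after the result was seen. By limma, 0 probe sets passed adjusted p under 0.05 for treatment under every alternative run. At unadjusted p under 0.05 limma gave 31 in the main fit, 214 with the replicate block and 118 without the 11-day pair. For days the count at adjusted p under 0.05 was 739 without vehicle 2 and 0 under every other alternative. All named genes kept their direction except those given here. In all, 18 values reversed, 16 lost their call and 20 counts moved, and 23 named slopes passed at unchanged size without vehicle 2.

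The count at unadjusted p under 0.01 for treatment (3) was 9 with no filter, 22 with the replicate block, 5 with days as a covariate, 23 without the 11-day pair and 16 with array weights. The replicate block changed no other call. The gene lists past the test for treatment (2) and days (3) were 5 and 6 with no filter, 1 and 1 at the upper 40%, 0 and 0 with an estimated correlation, and 0 and 11 without the 11-day pair. Quantile normalization left 1 for treatment. Leaving out 1 array gave 2 to 6 for treatment (6 without sAPPα 3, 4 without vehicle 3, and the 2 without vehicle 1 were choroid plexus and oligodendrocyte) and 3 to 6 for days (6 without sAPPα 1, 5 without vehicle 2 or vehicle 3).

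The camera adjusted p of the choroid plexus list was 0.825 with an estimated correlation, 0.0710 without the 11-day pair and 1.32e-08 to 0.110 without 1 array. That of the respiratory chain was 0.269 after quantile normalization, 0.825 with an estimated correlation, 0.132 without the pair and 0.00153 to 0.291 without 1 array. For days, the estimated correlation gave 0.901 for the microglial, oligodendrocyte and endothelial lists. The microglial list turned down without the pair (4.01e-12) and had 4.94e-07 to 0.0401 without 1 array. The oligodendrocyte list had 0.0554 at the upper 40% and 0.000570 to 0.0826 without 1 array. The endothelial list had 0.0595 with no filter, 0.161 at the upper 40%, 0.000121 to 0.294 without 1 array, and turned up without the pair (0.00925).

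Without the 11-day pair the log2 difference was -0.10 for App, -0.029 for Col8a1, -0.037 for Col6a2, 0.032 for Cort, -0.037 for Icam2 and -0.015 for Apbb1, and the slope was -0.023 for Cd9, -0.16 for Mpeg1 and -0.21 for Cd53. With array weights Col6a2 was at -0.067. Leaving out 1 array gave -0.54 to 0.67 for App, -0.0082 to 0.55 for Col8a1, -0.033 to 0.93 for Man1a, -1.0 to 0.24 for Neurod2 and -0.65 to 0.051 for Mvk. The cause was not tested for any of these. The robust fit and array weights were not run for camera, and at the upper 40% the choroid plexus list had too few members to test. The estimated correlation was run for camera only on all arrays, not with arrays left out. Without detection calls, signal over background could not be judged.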

Other observations

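None of the tests in this part was chosen after the result was seen. Of the gene lists that did not pass for days in culture, the glutamate receptor and postsynaptic list had 9 of 12 slopes negative (limma camera adjusted p = 0.242, median -0.16 per day). The respiratory chain list had 25 of 39 negative (adjusted p = 0.458). The cholesterol synthesis list had 11 of 16 positive (adjusted p = 0.301), the cell cycle list 17 of 31 (adjusted p = 0.465) and the choroid plexus list 4 of 6 (adjusted p = 0.854). Interneuron genes had 4 of 6 negative (adjusted p = 0.737), and neuronal genes 9 of 17 positive (adjusted p = 0.814). With an estimated correlation the adjusted p was 0.901 for each of these lists.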
